A study of Mus musculus with 2 samples.

How the data were processed

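H3K4me2, dimethylation of histone H3 at lysine 4, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in fetal mouse liver. Per the labels, the tissue was pooled liver of mixed-sex B6NCrl embryos at embryonic day 16.5, and there were 2 biological replicates of 1 condition. Replicate 2 came from 41 embryos and combined 2 technical replicates, per the labels. The number of embryos behind replicate 1 is not given in the sources used here.

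The authors deposited 4 peak lists in narrowPeak format on the mm10 build, per the labels and the readme files: 1 list for each replicate, 1 called on the pooled alignments of both, and 1 replicated list derived from the other 3. A possible control is listed in the labels, but whether the peaks were called against it, the peak caller, its version, the read depth and the rule for the replicated list are not given in the sources used here. All 39386 chromosomal peaks of the replicated list were identical in position to pooled peaks, and 36521 of them overlapped both replicates' own lists by at least 1 bp. Each deposited peak carries a signal value, which was taken as the authors' enrichment at that peak, on a scale whose reference is not given. It was used to describe, rank and filter peaks, and peaks of both replicates were set side by side by it to ask how closely their rankings followed each other and, as an alternative, in the replicate difference. The deposited −log10 p-value and −log10 q-value of each peak had minima of 2.02, 2.00, 2.02 and 2.07 for p in replicate 1, replicate 2, the pooled and the replicated list, so the lists hold weak peaks. A q above 0.05 was carried by 5.22% of replicate 1's peaks, 4.64% of replicate 2's and 0.155% of the replicated peaks. The files hold no read counts. Beyond the deposited p- and q-values, the precision of a peak's presence could be judged only from the spread between the 2 replicates. No control or untreated sample was analysed here.

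Peaks on chromosomes 1 to 19, X and Y were used, and those on other scaffolds were set aside. Genes were the 21851 protein-coding genes of GENCODE mouse release M21 with a protein-coding transcript in the basic set, on GRCm38.p6, the same build as mm10; no peak ended beyond its chromosome's end. A gene was called marked when a replicated peak lay within 1 kb of any of its transcription start sites (TSS). Breadth was the number of bases covered by a replicate's peaks within 5 kb of the gene's most covered TSS. Distal peaks lay more than 2.5 kb from every protein-coding TSS, and those within 50 kb of a gene's most upstream TSS were counted for it. CpG density of a gene was the highest number of CpG dinucleotides within 500 bp of any of its TSSs. Genes with more TSSs thus had more chances both of a high CpG density and of being marked. Domains were formed by joining replicated peaks less than 1 kb apart.

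With 1 sample on each side, no test between samples was possible. Overlap between replicates was set beside 100 shuffles of peak positions within chromosomes, avoiding assembly gaps. 15 lists of marker genes of liver, blood and other cell types and 1 class of olfactory and vomeronasal receptor genes were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 16 lists. Genes are not independent replicates, so these p-values describe these peak lists. Breadth, distal counts and replicate differences were given as the percentile of the list's median among 10000 random lists of the same size, and a list was said to stand apart at or above the 97.5 percentile or at or below the 2.5 percentile. Replicate differences were log2 ratios of covered bases, replicate 2 over replicate 1, with 100 bases added to each. For 14 transcription factor motifs, the central 500 bp of each distal replicated peak was paired with the window of closest GC content 5 to 20 kb away that overlapped no peak, and shares were compared by an exact two-sided McNemar test with Benjamini-Hochberg adjustment. Each motif was run beside its reversed, uncomplemented string as a control of the same composition. Errors are the SD of the 2 replicates, except where another spread is named.

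The lists, the comparisons of the report with their tests, and the rule for named genes were set before the data were examined. The tests of TSS coverage, of long domains by list, of repeated sequence, of developmental genes among unmarked promoters and of CpG density at hepatocyte genes were chosen after the values they concern had been seen. The rule takes from each list up to 4 members with the most covered bases and up to 3 unmarked members in alphabetical order, the 20 longest domains, the 10 genes with the strongest promoter peak, the 10 genes with the most distal peaks with 1 gene per group closer than 100 kb, and 10 key genes whatever their value (Alb, Afp, Hnf4a, Gata1, Hba-a1, Hbb-bs, Kit, Hbb-y, Cyp7a1 and Neurod1). Alternatives covered the overlap rule, a −log10 q of at least 5, equal numbers of strongest peaks, other windows, the pooled list, each replicate alone, and matching on CpG or TSS density. 1 alternative was added after seeing the data, leaving out genes with under 90% unique 50-mers. For this, 50-mers were taken every 25 bp within 1 kb of 1 TSS per gene. They were counted as exact matches in 65 chromosome and scaffold sequences on both strands. The TSS was the gene's most covered one, or the one of lowest coordinate in ties, so it was chosen from the same peaks. A gene's other TSSs were not scored. The erythroid gene Ahsp was absent from the annotation, which left 35 of 36 genes of that list.

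Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. The procedures were tested on simulated data. For lists of 35 genes among 21851, marks drawn with an odds ratio of 4 were detected at an unadjusted p under 0.05 in 86% of 200 runs, and with an odds ratio of 1 in 5%. For lists of 25 genes these shares were 74% and 3%, and most lists compared held fewer than 35 genes. Calls used adjusted p-values, for which detection was not simulated. For lists of 25 genes among 14234 marked ones, a 1.5-fold increase in covered bases was found in 87% of 100 runs. A GATA motif planted in 60 of 400 sequences was found in 93% of 100 runs, and its reversed control in 4%.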

Results

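H3K4me2, a histone mark of promoters and enhancers, was profiled in the liver of mouse embryos at embryonic day 16.5, when the organ holds both hepatocyte precursors and developing blood cells. The series has 1 group of 2 biological replicates, each a pool of livers. On the chromosomes, replicate 1 had 54968 peaks covering 47.6 Mb and replicate 2 had 53053 peaks covering 44.7 Mb, or 46.1 ± 2.04 Mb (SD, n = 2). The pooled list held 55480 peaks, and the authors' replicated list 39386 peaks covering 47981581 bp, 1.81% of the sequenced genome. Median peak widths were 463 and 464 bp in replicates 1 and 2 and 869 bp in the replicated list. Read depth was unknown.

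The comparison between the replicates asked how much of the H3K4me2 landscape was found in both pools. Of replicate 1's peaks, 74.6% overlapped a peak of replicate 2, and 81.7% of replicate 2's peaks overlapped a peak of replicate 1. These 2 directions of 1 comparison had a mean of 78.2% (SD 4.98 between directions, which is not a spread between replicates). Shuffled positions gave 3.22% and 3.36%. Over the 36452 regions found in both, signal values correlated across regions with a Spearman's rho of 0.926 and a Pearson's r of 0.941 on the log2 scale; regions are not independent replicates. Disagreement lay among the weak peaks. In the weakest of 10 equal groups by signal value, 35.2% of replicate 1's and 48.2% of replicate 2's peaks were shared, and in the strongest group 100% and 99.96%. The 13945 peaks found only in replicate 1 had a median width of 209 bp, against 749 bp for shared peaks, and 8.92% of them lay near a TSS, against 44.2%. For the 9724 peaks found only in replicate 2 the widths were 210 and 647 bp and the shares near a TSS 10.6% and 42.8%.

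**Figure D1:**
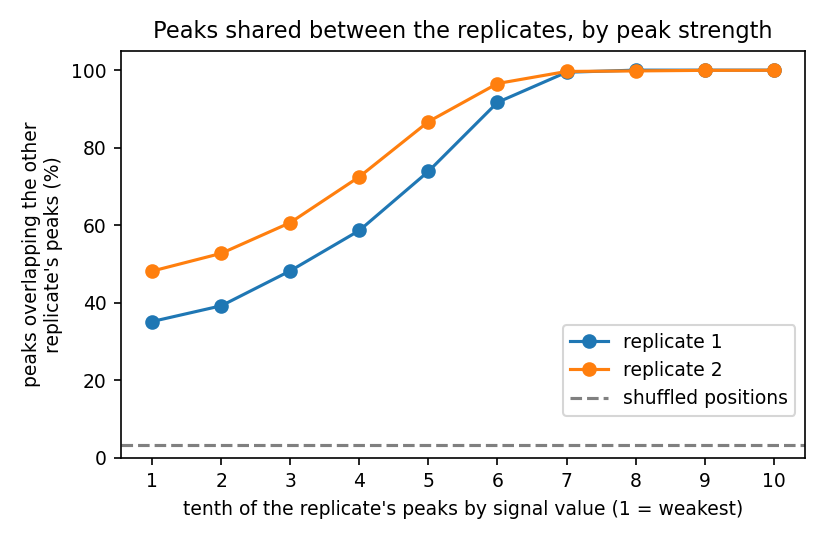
Share of each replicate's peaks that overlap a peak of the other replicate (%, vertical axis) in 10 equal groups of that replicate's peaks by signal value (horizontal axis, 1 is the weakest). Points joined by lines are the replicates and the dashed line is the mean of shuffled positions; sharing went from 35.2% and 48.2% in the weakest group to 100% and 99.96% in the strongest.

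H3K4me2 was concentrated at promoters. Of the replicated peaks, 38.1% had their midpoint within 1 kb of a protein-coding TSS, against 2.22% of shuffled positions, a 17.2-fold excess. In the replicates' own, longer lists this share was 32.1% ± 1.25 (SD, n = 2). Exons held 4.17% of the replicated peaks (shuffled 2.58%), introns 34.3% (shuffled 37.4%) and intergenic sequence 23.5% (shuffled 57.8%). Promoter peaks had a median width of 1560 bp and a median signal value of 23.0, against 583 bp and 5.64 for intronic and 602 bp and 6.35 for intergenic peaks. In all, 14234 of 21851 protein-coding genes (65.1%) were marked, and by the replicates' own lists 66.1% ± 0.0388 (SD, n = 2). Genes below the median promoter CpG density were marked in 32.5% of cases and the others in 97.1%.

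Genes of red blood cell formation and of blood progenitors were marked at almost all promoters, while genes of muscle, skin, lung and other epithelia were mostly unmarked. In the erythroid list 31 of 35 genes were marked, against 65.1% of all other genes (odds ratio 4.15, adjusted p = 0.00533, two-sided Fisher's exact test as in all list comparisons), with the same 88.6% in each replicate's own list. The blood progenitor list had 22 of 24 genes marked (odds ratio 5.89, adjusted p = 0.00824), and housekeeping genes 27 of 27 (adjusted p = 8.37e-05, exact tests). Housekeeping promoters are all CpG-dense, and within 2 strata of promoter CpG density split at the median that list no longer passed (100% against an expected 97.1%, adjusted p = 0.763, stratified permutation). The erythroid and progenitor lists did pass within these strata (odds ratios 7.44 and 8.93, adjusted p = 5.33e-04 and 0.0040, stratified permutation). The unmarked progenitor genes were Mpl, the thrombopoietin receptor, and Slamf1. Among the 4 unmarked erythroid genes were the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y, which are expressed in primitive red cells earlier in development. They were not free of nearby peaks. Hba-x had 1244 ± 70.7 covered bases within 5 kb (SD, n = 2), and a replicated peak lay 1246 bp from the TSS of Hbb-y. With a 2.5 kb window 32 of 35 erythroid genes were marked. The fourth unmarked gene, Slc25a37, a mitochondrial iron importer, was singled out after its values were seen. None of the 50-mers around its TSS was unique in the genome (0%), and neither replicate had a base covered within 5 kb. When genes with under 90% unique 50-mers were left out, 26 of 29 erythroid genes (89.7%, odds ratio 3.27, adjusted p = 0.0674) and 21 of 23 progenitor genes (91.3%, odds ratio 3.96, adjusted p = 0.0927) no longer passed Fisher's exact test. The lists' shares were close to those with all genes, while their sizes were smaller and the background was higher, at 72.6%. When a peak had to cover the TSS base itself, the erythroid odds ratio was 0.851 and that of housekeeping genes, 19 of 27, was 1.70 (adjusted p = 0.781 and 0.389, exact tests).

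In the hepatocyte list 22 of 30 genes were marked, which did not pass the test (odds ratio 1.47, adjusted p = 0.592, Fisher's exact test). Its broadest members were the transcription factor genes Prox1, with 7158 ± 513 covered bases, Onecut2 with 5884 ± 220, Cebpa with 5320 ± 448 and Tbx3 with 5180 ± 157 (SD, n = 2). By the replicates' own lists 24 and 25 of the 30 genes were marked, as 2 and 3 of the 8 unmarked genes had a peak in replicate 1 or 2. The first unmarked members in alphabetical order were Afp (alpha-fetoprotein), Ahsg and Alb (albumin). Alb, at chromosome 5, 90460897 to 90476602 (mm10), had 0 covered bases in both replicates within 5 kb of its TSS, and the nearest replicated peak lay 24996 bp away, between Alb and Afp at 90485893 to 90486431. That peak lay 4.31 kb from the TSS of Afp. Hnf4a, a regulator of hepatocyte identity, was marked, with 2504 ± 520 covered bases and 11 distal peaks within 50 kb. Its nearest replicated peak lay 981 bp from the closest TSS, just inside the 1 kb limit, and covered no TSS of the gene. Genes of mature hepatocyte metabolism were marked less often than others, 8 of 25 (odds ratio 0.251, adjusted p = 0.00284, exact test). Cps1, Cyp1a2 and Cyp2c29 were among its unmarked genes, as was Cyp7a1, the rate-limiting enzyme of bile acid synthesis, with 0 covered bases. Aldob, Fmo5, Gls2 and Car3 were its broadest members, with 2176 ± 225, 2169 ± 444, 1996 ± 129 and 1986 ± 145 covered bases. Within the strata of CpG density the hepatocyte list was marked more often (odds ratio 2.98, adjusted p = 0.0364, stratified permutation), and the mature list no longer passed (odds ratio 0.858, adjusted p = 0.883).

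Lists of the other blood and liver cell types fell on both sides of the background. Myeloid genes were marked in 7 of 26 cases (odds ratio 0.197, adjusted p = 3.01e-04) and lymphoid genes in 5 of 22 (odds ratio 0.157, adjusted p = 2.37e-04, exact tests). Adgre1, C1qa and C1qb, markers of macrophages, and Blnk, Cd19 and Cd3d, markers of lymphocytes, were among those without a peak. The broadest members were Prtn3 (4312 ± 639 covered bases), Cd68, Mafb and Irf8 of the myeloid list and Ebf1 (2694 ± 138), Bcl11b, Lck and Vpreb1 of the lymphoid list. The strongest replicated peak within 1 kb of a Cd68 TSS had a signal value of 3.07, against 6.58 for Prtn3, 18.7 for Mafb and 19.6 for Irf8. Covered bases count every peak within 5 kb, whichever gene it belongs to. Both depletions no longer passed within strata of CpG density (odds ratios 0.554 and 0.376, adjusted p = 0.402 and 0.236, permutation). Megakaryocyte genes were marked in 13 of 19 cases (adjusted p = 1, exact test), led in breadth by Nbeal2 (5554 ± 83.4), Itga2b, Gp9 and Gp5, with Clec1b, Gp6 and Ppbp unmarked. Within strata of CpG density they were marked more often (odds ratio 3.51, adjusted p = 0.0328, permutation). Endothelial genes (13 of 21, adjusted p = 0.937), stellate and mesenchymal genes (15 of 23, adjusted p = 1) and bile duct genes (12 of 15, adjusted p = 0.417) did not pass the exact test. Their broadest members were Ets1 (3012 ± 882), Esam, Kdr and Plvap of the endothelial list, Reln (5724 ± 473), Nr2f1, Pdgfra and Lhx2 of the stellate list, and Cd24a (5591 ± 202), Sox4, Hnf1b and Jag1 of the bile duct list. Unmarked were Cdh5, Clec4g and Emcn, then Acta2, Col3a1 and Colec10, and then Cldn4, Krt7 and Spp1.

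Of genes for tissues outside the liver, muscle and heart genes were marked in 1 of 23 cases (odds ratio 0.0243, adjusted p = 1.03e-08, exact test), the marked gene being Ryr1. Acta1, Actc1 and Casq1 were unmarked. Other epithelial genes were marked in 8 of 23 cases (odds ratio 0.285, adjusted p = 0.00716, exact test), with Cdx2, Gcg and Ins1 unmarked and Cela1 the broadest at 2874 ± 145. The muscle and other epithelial lists were also marked less often within strata of CpG density (odds ratios 0.0862 and 0.246, adjusted p = 0.0028 and 0.0328, permutation). Olfactory and vomeronasal receptor genes were marked in 3 of 1465 cases (odds ratio 8.88e-04, adjusted p below what the computation could hold). Neuronal genes were marked in 15 of 25 cases (adjusted p = 0.831) and developmental regulators, largely Hox and other patterning genes, in 17 of 35 (odds ratio 0.505, adjusted p = 0.0797, exact tests). Unmarked were Dcx, Gad1 and Gad2, and Barhl1, Hoxa2 and Hoxb1. Both lists are rich in CpG-dense promoters, with 72% and 88.6% of their genes above the median, and within strata of CpG density both were marked less often than other genes (odds ratios 0.265 and 0.109, adjusted p = 0.0040 and 5.33e-04, permutation). Without genes in repeated sequence the developmental list also passed the exact test (odds ratio 0.355, adjusted p = 0.00697).

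**Figure D2:**
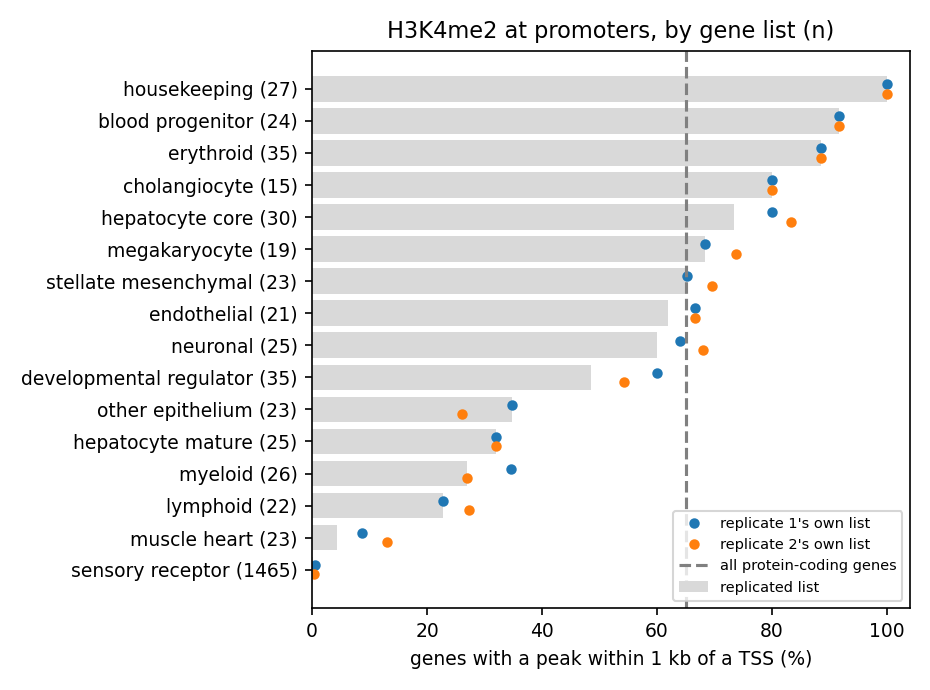
Share of each list's genes with a peak within 1 kb of a TSS (%, horizontal axis), by gene list with its number of genes (vertical axis). Bars are the replicated list, blue and orange points the own lists of replicates 1 and 2, and the dashed line is the 65.1% of all protein-coding genes; shares went from 100% of housekeeping genes to 0.205% of the receptor class.

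Among lists with at least 5 marked genes, H3K4me2 was broadest at erythroid and blood progenitor genes and narrowest at neuronal and other epithelial genes. The median covered bases within 5 kb of the TSS were 2359 over all marked genes and 5996 over the erythroid list, with medians of 6074 and 5623 in replicates 1 and 2. Blood progenitor genes had a median of 4623, housekeeping genes 3954 and hepatocyte genes 3543, at the 100, 100 and 99.9 percentiles of random lists, and the erythroid list was at the 100 percentile. In the erythroid list Epb41 and Ank1, of the red cell membrane skeleton, had 9578 ± 182 and 8481 ± 182 covered bases, and the transcription factor genes Nfe2 and Tal1 had 9425 ± 32.5 and 9002 ± 220 (SD, n = 2). Gata1, the central erythroid transcription factor gene on chromosome X, had 7710 ± 23.3. Meis1 (7128 ± 11.3), Runx1 (6738 ± 295), Lmo2 (6673 ± 158) and Ikzf1 (6511 ± 120) led the progenitor list, and Kit, the stem cell factor receptor, had 5522 ± 24.7. The adult globin genes Hba-a1 and Hbb-bs had 5204 ± 419 and 3087 ± 1363, in sequence where 31.6% and 56.96% of 50-mers were unique. Ubc, Cltc, Rpl3 and Polr2a led the housekeeping list with 5466 ± 156, 5462 ± 70.0, 5457 ± 291 and 5408 ± 295.

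Marked neuronal genes had a median of 927 covered bases, other epithelial genes 908 and developmental regulators 1428, at the 0, 0.05 and 0.14 percentiles. Neurod1, a neuronal transcription factor gene, had 672 ± 47.4, and Neurog2, Pou4f1, Map2 and Tubb3 had 2065 ± 2.83, 1707 ± 160, 1586 ± 20.5 and 1540 ± 61.5. Pax6 (3130 ± 48.8), Six1, Hoxa1 and Otx1 were the broadest developmental regulators. Stellate (1460, 0.675 percentile) and endothelial genes (1456, 1.10 percentile) were also narrow. The medians of the mature hepatocyte (1845), megakaryocyte (1760), myeloid (2214), lymphoid (2506) and bile duct (1935) lists lay within the central range of random lists. The megakaryocyte list was narrow within 2 kb (0.720 percentile), in replicate 2 alone (2.42 percentile) and with a −log10 q of at least 5 (2.16 percentile), as was the mature hepatocyte list with that threshold (0.800 percentile). The position of the hepatocyte list depended on the flanks and on weak peaks: within 2 kb of the TSS it was at the 39.7 percentile, and with peaks of −log10 q of at least 5 at the 82.7 percentile. Other epithelial genes did not stand apart in replicate 2 alone (4.63 percentile), nor developmental regulators with a 20 kb window (2.60 percentile).

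**Figure D3:**
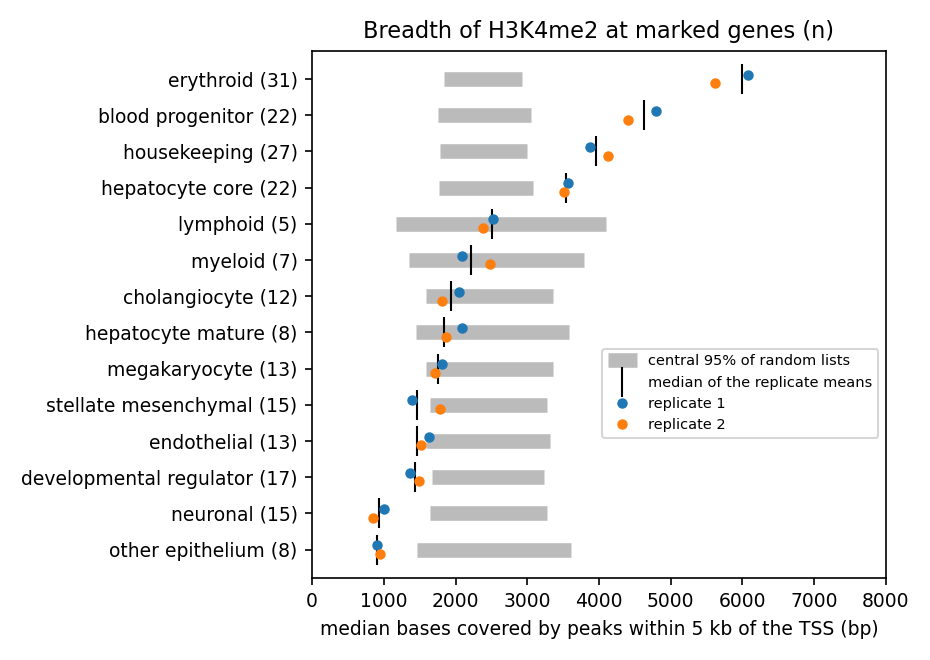
Median bases covered by peaks within 5 kb of the TSS (bp, horizontal axis) over the marked genes of each list with at least 5 such genes (vertical axis, number of genes in brackets). Black ticks are medians of replicate means, blue and orange points are replicates 1 and 2, and grey bars span the central 95% of random lists; the erythroid median of 5996 bp lay highest and the other epithelial median of 908 bp lowest.

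The longest stretches of H3K4me2 included 5 genes of the erythroid list, Ank1, Nfe2, Epb41, Zfpm1 and Fech. Joining peaks less than 1 kb apart gave 28974 domains with a median length of 1256 bp, of which 1224 were over 5 kb. The longest contained the TSS of Ank1 and spanned 34746 bp on chromosome 8, 23026885 to 23061630, with 31334 ± 848 bases covered (SD, n = 2). It was followed by domains at Ranbp10 and Tsnaxip1 (25.6 kb), at Cbx5, Hnrnpa1 and Nfe2 (23.5 kb), at Epb41 and Gm10300 (22.4 kb), at Rbm38 (21.3 kb) and at Picalm (20.9 kb). Next came Zfpm1, a GATA1 cofactor gene (16.8 kb), Lmo2 (16.7 kb), the region of Gm49661, Junb, Prdx2 and Rnaseh2a (16.6 kb), and that of Stradb and Trak2 (16.4 kb). The remaining 10 lay at Zc3hav1, St3gal5, Nt5c3 with Vmn1r4, Gpr146, Cdkn1b, Fech (the last enzyme of haem synthesis), Sema4b, Bmp2k, Galnt10 and Lpcat1, and the shortest of them was 14029 bp. Of these 20 domains, 6 were touched by the 20 longest single peaks without joining. The promoter peaks with the highest signal values were at Cnnm2 (93.8 in the replicated list, 73.8 ± 0.702 in the replicates' own, SD, n = 2), Zbtb46 (86.4), Rusc1 (81.1), Syce2 (80.3), Runx1 (80.1), Mpp5 (79.5), Cdc42ep3 (78.7), Foxo3 (78.6), Dennd2c (78.5) and Ivns1abp (78.3).

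**Figure D4:**
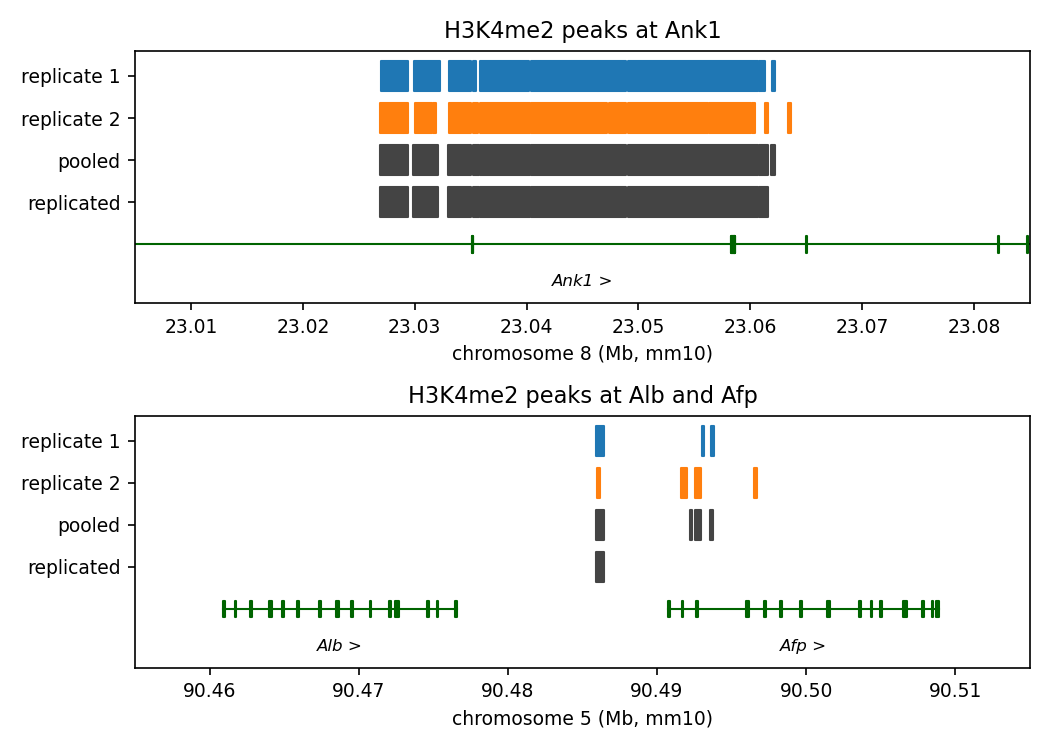
Peaks of the 4 lists (boxes, rows) along chromosome 8 around Ank1 and along chromosome 5 around Alb and Afp (horizontal axes, Mb, mm10), with genes in green, exons as ticks and arrowheads giving the strand. The Ank1 domain spans 34746 bp in the replicated list, while 1 replicated peak lies between Alb and Afp and none at either TSS.

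Distal peaks were most numerous around erythroid and hepatocyte genes. Of the replicated peaks, 19282 were distal. The median number within 50 kb was 5 for erythroid genes and 3.5 for hepatocyte genes, both at the 100 percentile of random lists, whose typical median was 1. Some members are neighbours with overlapping windows, such as Hbb-bs, Hbb-y and Hbb-bh1 with 25 each, and Fga, Fgg and Fgb with 10, 10 and 11. Random lists were drawn without regard to such clusters, so the percentiles take no account of peaks counted more than once. Blood progenitor genes (median 2, 98.6 percentile), developmental regulators (2, 98.9 percentile) and housekeeping genes (2, 97.9 percentile) also stood apart, and the receptor class lay below (0, 0.655 percentile). For developmental regulators this was lost with a 20 kb window (49.3 percentile) and with either replicate's own list (86.8 and 90.8 percentiles), for the receptor class with a 20 kb window (50 percentile), and for housekeeping genes on matching for TSS density (96.9 percentile). Medians of the other 10 lists did not stand apart: 2 for megakaryocyte and endothelial genes, 0 for stellate genes and 1 for the remaining 7. Endothelial genes did so with either replicate's own list (98.4 and 97.6 percentiles) and by covered bases (99.4 percentile). The gene with the most distal peaks was Hbb-bh1, in the beta-globin cluster on chromosome 7, with 25; Hbb-bs, Hbb-y and Hbb-bh2 had the same count. The replicates' own lists held 28 ± 5.66 there (SD, n = 2). Ell2 had 23, Hectd4, Hist1h4f and Zfpm1 had 18, Picalm, Pim1, Rreb1 and Usp32 had 17, and Cenpt had 16.

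GATA motifs distinguished distal peaks from their surroundings. The sequence AGATAA was found in 27.9% of 19281 distal peaks and in 16.6% of their GC-matched flanks, a ratio of 1.69 (adjusted p = 3.55e-164, exact McNemar test), while its reversed string had a ratio of 0.964. A composite of a partial E-box and a GATA site, bound by TAL1 with GATA1, was found in 8.05% against 2.76%, a ratio of 2.92 (adjusted p = 5.50e-120, exact test). Motifs of KLF factors (22.2% against 17.7%, adjusted p = 3.93e-30), FOXA (6.57% against 4.92%, adjusted p = 9.31e-12), RUNX (3.71% against 2.69%, adjusted p = 2.47e-08) and CTCF (0.975% against 0.425%, adjusted p = 1.91e-10) were also more frequent in peaks by the exact test. The RUNX motif did not pass against flanks of any GC content (ratio 1.08, adjusted p = 0.214) and that of CTCF not in the central 200 bp (ratio 1.53, adjusted p = 0.0559, exact tests). Reversed strings of the KLF and FOXA motifs were themselves more frequent in peaks, with ratios of 1.07 and 1.12 (adjusted p = 0.00656 for both, exact tests). The reversed string of the PU.1 and ETS motif was less frequent in peaks (ratio 0.843, adjusted p = 0.00656, exact test). Controls thus moved in both directions. The motif of the hepatocyte factor HNF4A was found in 1.42% against 1.09% (adjusted p = 0.00517), and did not pass with either replicate's own list (ratios 1.17 and 1.18, adjusted p = 0.0651 and 0.0549, exact tests). The C/EBP motif had a ratio of 1.36, below the 1.55 of its reversed control. The order turned in replicate 1's own list (1.54 against 1.41) and in the central 200 bp (1.44 against 1.43). The motif stayed below its control in replicate 2's own list (1.44 against 1.63), over whole peaks (1.40 against 1.51) and against flanks of any GC content (1.11 against 1.21). Ratios were 1.17 for PU.1 and ETS, 1.11 for AP-1 and NFE2, 1.24 for OCT, 1.36 for MEF2 and 4.00 for HNF1, the last from 12 peaks and 3 flanks. The HNF1 ratio was 1.75 in replicate 2's own list (adjusted p = 0.591) and 1.33 against flanks of any GC content (adjusted p = 0.715, exact tests), and OCT, MEF2, C/EBP and HNF4A did not pass against such flanks either (adjusted p = 0.248, 0.729, 0.172 and 0.172, exact tests). In replicate 1's own list OCT and the AP-1 and NFE2 motif did not pass (adjusted p = 0.0843 and 0.0549, exact tests). By the exact test 13 of 14 motifs had an adjusted p under 0.05, REST being the exception (ratio 0.960, adjusted p = 0.830), although in the central 200 bp it was less frequent in peaks (ratio 0.571, adjusted p = 0.0214).

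**Figure D5:**
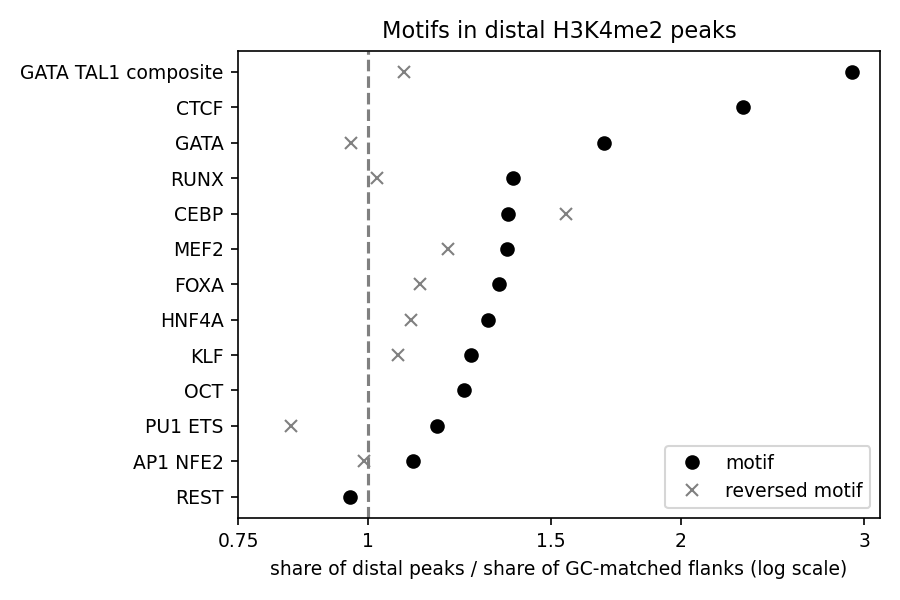
Share of distal peaks with a motif divided by the share of GC-matched flanks (horizontal axis, log scale), by motif (vertical axis); HNF1, with few occurrences, is not drawn. Black points are motifs and grey crosses their reversed strings where at least 50 flanks held one; the GATA and TAL1 composite had the highest ratio, 2.92, and C/EBP lay below its control.

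Whether any cell lineage differed between the 2 pools was asked from the log2 ratio of covered bases, replicate 2 over replicate 1. Over genes marked in either replicate its median was -0.05. The hepatocyte list had a median of -0.16 (0.29 percentile of random lists) and the endothelial list -0.24 (0.05 percentile), so both were covered less in replicate 2 than random lists were. With equal numbers of strongest peaks in each replicate they were at the 22.9 and 16.1 percentiles, and by the highest signal value near the TSS the hepatocyte list was at the 99.98 percentile, the opposite side. The receptor class (-0.21, 11 genes) and the muscle list (0.80, 4 genes) also stood apart, the receptor class not with equal numbers of peaks (49.97 percentile). The muscle median was 0.23 with 500 bases added in place of 100, and 2 of its 4 genes lay above the median of all genes. The erythroid list was at the 3.48 percentile (1.98 with 500 bases added in place of 100, 1.80 by signal value and 5.40 with equal numbers of peaks), and the blood progenitor list at the 16.3 percentile. By signal value the other epithelial and neuronal lists also stood apart, at the 1.77 and 98.9 percentiles. These values compare 2 libraries and have no replicate check.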

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

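No test was run for this part. Peaks were also present on sequences left out of all comparisons. The replicated list held 10 peaks on 5 unlocalized or unplaced scaffolds, with a highest signal value of 22.4, and replicates 1 and 2 held 13 each. They were noted because these scaffolds carry signal that no comparison used. No explanation was tested.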

How the results depend on the processing

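The alternative that leaves out repeated sequence was chosen after seeing the data. Overlap between replicates was 71.7% when 50% of a peak had to be covered and 88.3% with a −log10 q of at least 5. Spearman's rho was 0.930 with that threshold and 0.934 with the −log10 p. The promoter share of peaks was 49.2% with a 2.5 kb window, 29.6% in the pooled list, 42.0% with a −log10 q of at least 5, and 31.2% to 33.0% with either replicate alone; wider windows take in more peaks by construction. Of the 20 longest domains, 6 were kept without joining and 8 with joining up to 3 kb. Motifs past the threshold numbered 7 with any flank, whose GC content of 45.0% lay below the peaks' 50.1%. Lists standing apart between replicates numbered 1 with equal numbers of peaks, against 4. The number of lists past the threshold at promoters (9), in breadth (9) and in distal peaks (6) stayed within 1.5 times under every alternative run, although members changed. Odds ratios that turned direction at promoters were, at the TSS base, erythroid (0.851), hepatocyte (0.548), megakaryocyte (0.645) and stellate genes (0.782), with a −log10 q of at least 5 megakaryocyte (0.953) and stellate genes (0.865), in unique sequence megakaryocyte (0.816) and stellate genes (0.706), endothelial genes with a 2.5 kb window (1.25) and within CpG strata (1.38), and neuronal genes in the pooled list (1.57). With either replicate alone they were 1.02 to 1.03 for endothelial, 0.911 to 1.09 for neuronal and 0.960 to 1.17 for stellate genes. Apart from the erythroid one, none of these passed the test in either setting. Motif ratios that turned were HNF1 in the central 200 bp (1.00), OCT (0.916) and REST (1.10) with any flank, and REST with replicate 1 alone (range with either replicate alone 1.00 to 1.11, the lower value being level). Some percentiles crossed the middle between the main setting and an alternative and were past a limit in at least 1 of them. They were the hepatocyte breadth within 2 kb (39.7), the developmental regulators' distal count within 20 kb (49.3) and the hepatocyte replicate difference by signal value (99.98). The receptor class's breadth also crossed with either replicate alone (0 to 0, other genes entering). Crossings between alternatives are not listed. Of 135 list odds ratios recomputed, 110 kept direction and side of the threshold, 15 turned direction, 5 lost and 5 gained a call; the housekeeping list, whose odds ratio was infinite, lost its call in 2 of 9 alternatives. Except where the construction is named, the cause was not tested. Depth is unknown, so absence of a peak does not show absence of the mark.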

Other observations

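The tests of TSS coverage, of long domains, of repeated sequence, of developmental genes among unmarked promoters and of CpG density at hepatocyte genes were chosen after the values they concern had been seen. Long domains are built from much the same peaks as breadth, so their counts by list largely restate the breadth result and are not separate evidence. Erythroid genes were over-represented among the 1288 genes with a TSS in a domain over 5 kb: 20 of 35, against 5.81% of other genes (odds ratio 21.6, adjusted p = 2.47e-15, two-sided Fisher's exact test over 16 lists). Blood progenitor genes followed with 9 of 24 (adjusted p = 2.60e-05) and hepatocyte genes with 9 of 30 (adjusted p = 1.55e-04), while none of the 35 developmental regulators had one (0, adjusted p = 0.612, exact tests). Peak summits lay downstream of the nearest TSS in 66.5% of the 19425 cases within 2.5 kb. Among marked genes the TSS base itself was covered in 89.4%, but in 19 of 31 erythroid (adjusted p = 6.18e-04), 13 of 22 hepatocyte (adjusted p = 0.00178) and 19 of 27 housekeeping genes (adjusted p = 0.0164, Fisher's exact tests). The shares were also lower for mature hepatocyte genes (4 of 8), other epithelial genes (4 of 8) and myeloid genes (3 of 7, adjusted p = 0.0164 each) and for lymphoid genes (2 of 5, adjusted p = 0.0229, exact tests). Progenitor genes, 20 of 22, did not pass (adjusted p = 1, exact test), and marked genes of low CpG density had 79.5% in all. Chromosome X held 6.47 replicated peaks per Mb, below every autosome, whose median was 16.1, with the lowest value on chromosome 14 and the highest, 26.5, on chromosome 11.

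The plasma protein genes Alb, Afp, Ahsg, Apoa1, Apoc3, Fgb, Serpina1a and Ttr made up the 8 unmarked hepatocyte genes (the last 5 chosen after their values were seen), while other plasma protein genes of the list, such as Vtn and Apoa2 (chosen in the same way), were marked. Of the 8, 7 had peaks within 5 kb of the TSS, Alb being the exception, and 25 of the 30 hepatocyte genes were marked with a 2.5 kb window. Repeated sequence at the scored TSS accounts poorly for this set, since 12.5% of them (Serpina1a) had under 90% unique 50-mers there. Low CpG density stays open: all 8 lay below the median, against 11 of the 22 marked genes (two-sided Fisher's exact p = 0.0140), and low-CpG hepatocyte genes were marked more often (57.9%) than all low-CpG genes (32.5%), though less often than the erythroid ones (87.5%, p = 0.0383, exact test). Another candidate explanation that stays open is that hepatocytes are a minority of the cells, as the peaks at marked low-CpG hepatocyte promoters had a median signal value of 8.73 against 19.3 at erythroid ones (two-sided permutation p = 0.00476), while a lower level of the mark per hepatocyte was not tested.

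Among the 5473 genes with at least 75 CpG dinucleotides within 500 bp of a TSS, 78 were unmarked. Genes there with under 90% unique 50-mers were unmarked more often (20 of the 78, against 1.78% of the marked genes; odds ratio 19.0), so loss of reads that map to several places is a candidate explanation for those, Slc25a37's neighbours Entpd4 and Entpd4b among them (both chosen after their values were seen). The scored TSS was chosen from the same peaks, so this odds ratio carries that choice. The other 74.4% of the unmarked genes were unique at the scored TSS, which argues against such loss of reads there. Their other TSSs were not scored, so loss of reads at those was not tested. Of the 58 unique unmarked genes, 6 belonged to the neuronal or developmental lists, against 13 of the 5299 marked unique genes (0.245%, odds ratio 46.9, Fisher's exact p = 3.01e-08). That genes of other lineages lack the mark is a candidate explanation for these 6, untested for the others. More members of these lists with such promoters were marked (13) than unmarked (6), so membership alone does not account for it. The test also partly repeats the lower shares of both lists within strata of CpG density.

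Peaks found in a single replicate may be noise or weak elements. Their distal members held more GATA motifs than GC-matched flanks, 1.47 times in replicate 1 and 1.27 times in replicate 2 (exact McNemar p = 5.48e-29 and 7.80e-08), against reversed controls of 1.02 and 1.01. Noise placed without regard to real elements would give a ratio near 1, and these values argue against that for the set as a whole. Noise close to shared peaks could give a higher ratio. Distance to shared peaks was not matched between peaks and flanks, so this kind of noise was not tested. Shared peaks had ratios of 1.68 and 1.64. A mixture of noise and weak elements stays open, and no biological difference between the pools was tested.

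It was also asked, before the values were seen, whether GATA motifs were more frequent in distal peaks near erythroid than near hepatocyte genes. They occurred in 42 of 171 and 19 of 96 peaks (odds ratio 1.32, two-sided Fisher's exact p = 0.448), and HNF4A motifs in 3 and 0. Against all other distal peaks those near erythroid genes held GATA motifs in 24.6% against 28.0% (odds ratio 0.838, p = 0.347, exact test). The peaks are too few to decide.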
